A study of Drosophila melanogaster and Drosophila persimilis and Drosophila pseudoobscura with 5 samples.

How the data were processed

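Johnston's organ, the hearing organ of the fly antenna, was sequenced as RNA from adult flies of D. melanogaster, D. simulans, D. yakuba, D. pseudoobscura and D. persimilis, with 1 library per species. Per the labels, flies were kept at 25 degrees Celsius, RNA was taken with a micro-scale column kit, and libraries followed the usual Illumina procedure. Sex, the number of antennae and the number of flies are not given in the sources used here. TopHat2 2.0.3 and HTSeq are named in the submitters' processing notes, without the role of each. Strand and multiple-mapping settings are not given in the sources used here, so that reads from overlapping genes, from near-identical gene copies and from opposite strands cannot be told apart.

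The deposited count values of each library are whole numbers of reads per gene of that species' own annotation, release 5.46 for D. melanogaster, 1.4 for D. simulans, 1.3 for D. yakuba, 2.30 for D. pseudoobscura and 1.3 for D. persimilis per the labels. They have no normalization. The total counts were 22391819, 7580214, 13916387, 12908479 and 9236301 in that order. Genes of different species carry different identifiers here, so counts were used for depth, for the most abundant genes of each library and for the D. melanogaster counts of hearing genes, with 95% exact Poisson intervals. A count of 0 was taken to allow up to 3 reads. Intervals and this limit cover counting error only.

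The deposited signal values come from the authors' table of 8180 genes in all 5 species under D. melanogaster symbols. The labels do not describe this signal, and what it holds was worked out from the deposited values. The 75th percentile was 34.3366 in every library. For 5842 genes with a D. melanogaster count above 20, the value times exon length divided by the count lay within 5% of its median for 76.8%. Each of the 1353 genes at 0 in D. melanogaster with a matched identifier had a count of 0. The values were therefore read as reads divided by gene length, scaled to the same upper quartile. How the authors matched genes between species is not given in the sources used here, so a match to another copy of a gene family cannot be told from a difference in level. Outside D. melanogaster a value of 0 can be a missing match. In D. melanogaster the 1353 genes had a count of 0, which reads left out at overlapping genes can also give. Genes at 0 in any library are described as listed at 0, and no fold is given against them. They enter the calls, medians and percentiles below as low values, except where genes above 0 in all libraries are named. The table had 1397, 2321, 1710, 2145 and 2197 values of 0 in the 5 libraries, and 782 genes at 0 in all of them.

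All values were multiplied by 1 common factor, 1.09093, which keeps the authors' scaling between libraries, and taken as log2(value + 1). This pseudocount understates the differences of low genes. Genes with a mean of at least 5 over the 5 libraries were compared, 5089 in number, of which 4507 were above 0 in all 5 libraries and 582 were at 0 in some. Gene symbols were matched to the BDGP6 annotation, which is a later assembly than the authors' release, by current symbol (6465 genes) or older symbol (1622), 8087 in all, of which 30 share an identifier. It supplied exon lengths, overlaps between genes and the coordinates of named genes, looked up by gene identifier.

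With 1 library per species there was no replicate within a species, and species were not taken as replicates of a group, so no test was run and no p-value was computed. A gene was called higher in the obscura group when the lower of its 2 libraries exceeded the highest of the other 3 by at least 2-fold, and lower by the mirror rule. The same gap was counted for all 10 ways to part 5 libraries into 2 and 3. Pairs of libraries were compared by the number of genes at least 4-fold apart and by Spearman correlation across genes. D. yakuba was compared with both D. melanogaster and D. simulans, taking the smaller of both differences, and its lists with the mean of both. The placement of species into groups is textbook phylogeny, and was not tested here.

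Gene lists were fixed before the data were examined, as were the groups, the comparisons, the thresholds and the alternatives not named as later below. They covered mechanosensory channels, axonemal dynein and its assembly, ciliogenesis, chordotonal support, chordotonal and antennal transcription factors, phototransduction, other eye and pigment genes, synapse, glia, the olfactory segment, muscle, fat body, haemocytes, immune response, heat shock and stress, detoxification, the respiratory chain, the circadian clock, housekeeping references, germline and reproductive tract, and cytosolic ribosomal proteins. For the 18 lists with at least 5 compared members, the median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list outside percentiles 2.5 to 97.5 was said to stand apart. The percentile describes these libraries and is not a p-value. Of 90 combinations of list and contrast 33 stood apart. The 4.5 that would do so by chance holds only for members that vary independently, which members of a list need not do. The contrasts also share libraries, so 33 against 4.5 does not measure an excess. Members were called by the 2-fold gap in the contrast of species groups and by 4-fold in the others. The lists share Cyp6w1 (olfactory and detoxification), GstD1 (heat shock and detoxification), Ir25a (olfactory and clock), SdhA (respiratory chain and housekeeping), nrv2 (chordotonal support and glia) and takeout (fat body and clock).

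Named genes followed a rule fixed beforehand: the 12 largest gaps in each direction between species groups, the 10 largest differences in each direction in the other comparisons among genes with a gene name, the 10 highest means, the most abundant genes of each library, members of the lists and 8 hearing genes. Members of lists were named as examples, and not all that the rule allowed are given. Not all genes that the rule took for D. yakuba are reported here. A gene was taken to have a name when its current or tabulated symbol is not a plain CG or CR number, which holds for 3308 of the 5089 genes. This reading, and a further set of the same size among genes above 0 in all 5 libraries, were chosen after seeing the data. Genes without a name were passed over, such as 5 of the 12 largest gaps upward and 4 of the 12 downward in the obscura group.

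The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 20, genes above 0 in all libraries, equal library totals, TMM factors from edgeR 4.0.16 in R 4.3.3, median-of-ratios factors, a 4-fold gap, a 2-fold threshold for pairs, Pearson correlation, unmatched random lists and each library left out in turn. Equal totals shifted the median log2 value by 0.52 in D. melanogaster, -0.35 in D. simulans, 0.26 in D. yakuba and -0.32 in D. persimilis, and median-of-ratios scaling shifted D. melanogaster by -0.13. Chosen after seeing the data were a restriction to genes of middle exon length (above 1183 and below 2901 bases), the lists with each library left out of its group mean, the lists of D. yakuba against D. melanogaster alone, and the lists and families with a cubic trend on log2 exon length removed. The calculation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

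The species-group comparison was tested on simulated data for the 5089 genes with a coefficient of variation of 0.3 and 200 changed genes. It recovered 7% of genes raised and 7% of genes lowered 2-fold, 81% and 69% at 4-fold, and 100% and 98% at 8-fold, and called 3, 1 and 2 unchanged genes. The simulated libraries had no trend on gene length, no missing matches and no difference in tissue content. Their noise was set and not estimated from these libraries, in which splits other than the species groups held 50 to 308 genes. The few unchanged genes called are therefore no estimate of false calls here. A list of 20 genes raised 8-fold reached percentile 100, and 4 of 100 unchanged lists of independently varying genes stood apart.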

Results

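Johnston's organ, the hearing organ in the second segment of the fly antenna, was profiled by RNA sequencing in adults of 5 Drosophila species. D. melanogaster, D. simulans and D. yakuba belong to the melanogaster species group, and D. pseudoobscura and D. persimilis to the obscura group. Each species was represented by 1 library. No difference below therefore has a replicate check, no p-value was computed, and "higher" and "lower" refer to these libraries. Tissue from outside the organ was not measured, so a difference can also come from the tissue that a library held. The sex of the flies is not given in the sources used here, so a difference in sex between libraries cannot be told apart either. The reads counted on genes came to 22391819 in D. melanogaster, 7580214 in D. simulans, 13916387 in D. yakuba, 12908479 in D. pseudoobscura and 9236301 in D. persimilis. At least 1 read was counted on 11074, 9378, 10815, 9747 and 9989 genes in the same order. Levels between species are given as the authors' length-corrected signal from a table of 8180 genes under D. melanogaster symbols, and 5089 of these genes were expressed highly enough to be compared. Where signals are listed without species names they are in the order D. melanogaster, D. simulans, D. yakuba, D. pseudoobscura, D. persimilis.

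Among genes of the cross-species table, Obp19d, an odorant-binding protein, had the highest mean signal over the 5 libraries, 27278, with levels of 21798, 13449, 21937, 53630 and 25575. ATPsynC, the ring subunit of the mitochondrial ATP synthase, followed with a mean of 19627. The others among the 10 highest were the cuticular protein Cpr65Au (13353), the antennal dehydrogenase Antdh (12295), the respiratory complex subunit ND-MLRQ (11635), the ribosomal protein RpL39 (11056), cytochrome c (Cyt-c-p, 9679), the odorant-binding proteins Obp28a (9567) and Obp83a (8843), and the cytochrome c oxidase subunit COX7B (8819). In the D. melanogaster counts the leading genes were CG8369 (529050 reads), Obp19d (367821), the arginine kinase Argk1 (282703), ATPsynC (198466) and the yolk protein Yp1 (196109). CG8369 and Argk1 were not among the genes of the cross-species table. The leading identifiers of the other libraries had no gene name in the sources used here, and held 119532 reads in D. simulans, 172301 in D. yakuba, 337748 in D. pseudoobscura and 154627 in D. persimilis.

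Genes with known roles in hearing ranged from no reads to 1100 reads in D. melanogaster. The mechanotransduction channel nompC (2L:5346200-5365760 in BDGP6) had 182 D. melanogaster reads (95% exact Poisson interval 157 to 210) and signals of 1.54, 0.932, 1.87, 2.91 and 0.959 in the 5 libraries. The TRPV channel subunit nan (3L:14186249-14189648) had 639 reads (590 to 691) and signals of 14.7, 0.0910, 12.98, 7.80 and 7.78, so that its level in D. simulans stood far below the others. Its partner inactive (iav, X:6813978-6818156) had 1100 reads (1036 to 1167), the ciliary dynein heavy chain beethoven (btv, 2L:17962625-17982472) had 144 (121 to 170) and the dynein assembly factor touch insensitive larva B (tilB, X:22449737-22451463) had 224 (196 to 255) in D. melanogaster, and these 3 were not among the genes of the cross-species table. nompA (2R:11310335-11318676), which encodes a matrix protein linking chordotonal dendrites to the cuticle, had 12 reads (6.20 to 20.96) and signals of 0.150, 0.396, 0.689, 5.52 and 0.158. No read was counted on the proneural gene atonal (ato, 3R:8278052-8279274) in D. melanogaster, which allows up to 3 reads, and it was listed at 0 in all 5 libraries. No value could be assigned to fd3F. The intervals cover counting error only.

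Of all the mechanosensory channels on the list fixed beforehand, 4 genes passed the expression filter, too few for a comparison of the list. They were nan, the TRPA channels pain (63.8, 19.5, 48.8, 6.29 and 6.46) and water witch (wtrw; 85.0, 7.32, 82.1, 78.3 and 29.0), and the DEG/ENaC channel ppk (11.99, 15.7, 15.9, 22.3 and 22.1). Of the eye and pigment genes outside phototransduction 3 passed, the tryptophan oxygenase vermilion (v; 23.6, 124, 47.6, 52.2 and 82.2), the GTP cyclohydrolase Punch (Pu; 42.8, 10.3, 20.01, 145 and 76.5) and the receptor ligand boss (9.90, 7.72, 23.0, 22.8 and 8.65). Of the germline and reproductive tract genes 4 passed. The eggshell genes Cp15 (6.35, 1000.0, 47.3, 0 and 93.3), Cp18 (1.21, 42.1, 2.36, 0 and 0) and Cp19 (0.804, 90.4, 2.58, 0 and 0) were highest in D. simulans, and grk, which encodes an oocyte ligand, was highest in D. persimilis (7.24, 13.9, 2.73, 21.01 and 72.9).

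The first question was whether the transcriptomes of the organ grouped as the species do. The 2 obscura group libraries had the highest Spearman correlation, 0.806 across the 5089 genes, with 774 genes at least 4-fold apart. D. melanogaster and D. yakuba, which correlated at 0.751, had fewer such genes, 592, and also fewer at least 2-fold apart, 1757 against 2021. The correlation was 0.724 for D. simulans and D. yakuba, with 1024 genes 4-fold apart. D. simulans, the closest relative of D. melanogaster among these species, correlated with it at 0.678 with 1138 genes apart, close to the 0.673 between D. yakuba and D. pseudoobscura with 1082 genes. Among genes above 0 in all libraries these 2 pairs were further apart, at 0.741 (800 genes) and 0.702 (786 genes). The remaining pairs between the species groups lay at 0.632 for D. melanogaster and D. pseudoobscura (1132 genes), 0.593 for D. melanogaster and D. persimilis (1397), 0.633 for D. simulans and D. pseudoobscura (1401), 0.663 for D. simulans and D. persimilis (1331), and 0.649 for D. yakuba and D. persimilis (1284). Correlations are across genes, which are not independent replicates. D. simulans was also the library with the fewest reads (7580214). Its difference from D. melanogaster followed exon length (Spearman correlation -0.325, against 0.0251 for D. yakuba). Its lower correlation with D. melanogaster is thus no measure of divergence of the organ alone.

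**Figure D1:**
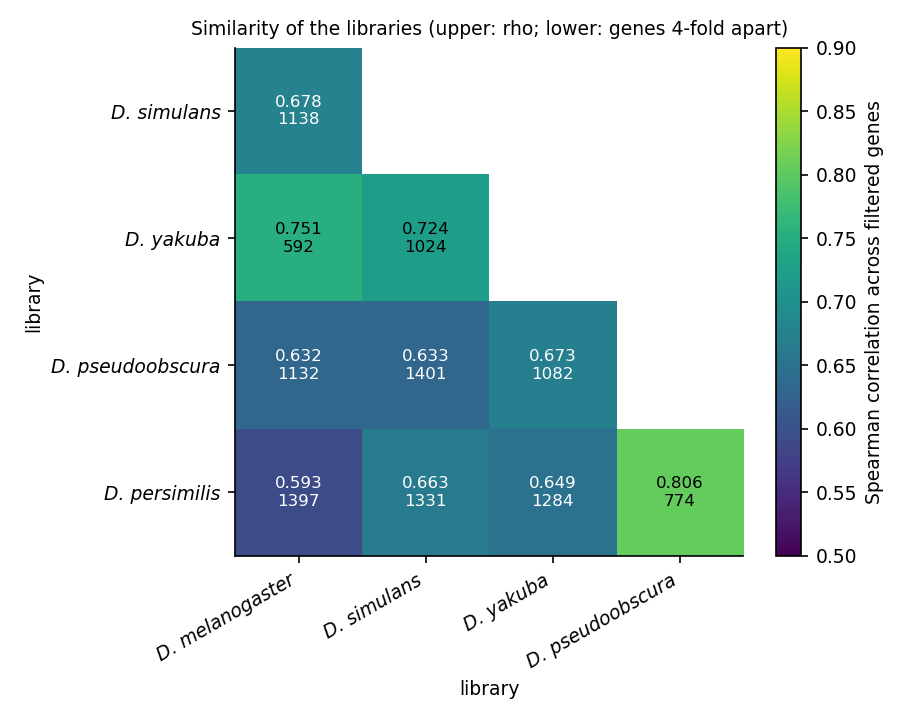
Spearman correlation across 5089 genes (colour scale and first value in each box) and number of genes at least 4-fold apart (the value below it) for each pair of the 5 libraries, with the library names on both axes. The D. pseudoobscura and D. persimilis pair has the highest correlation, 0.806, and the D. melanogaster and D. persimilis pair the lowest, 0.593.

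Of the 10 ways to part the 5 libraries into a pair and the other 3, the split between the species groups held the most genes, with 536 genes separated by a gap of at least 2-fold. The split that set D. melanogaster and D. yakuba against the rest came next with 308, and D. simulans with D. persimilis against the rest had 205. D. melanogaster with D. simulans gave 185, D. simulans with D. yakuba 174, D. melanogaster with D. pseudoobscura 109, D. simulans with D. pseudoobscura 80, D. yakuba with D. persimilis 74, D. yakuba with D. pseudoobscura 61 and D. melanogaster with D. persimilis 50. The species-group split exceeded the next by a ratio of 1.74. With each library scaled to the same total the order turned, with 507 genes for the species groups against 513 for D. melanogaster and D. yakuba, a ratio of 0.988. The ratio was 4.61 without the D. simulans library and 1.01 without D. persimilis, and lay between these without each of the others. Leaving out a library changes the kind of split, so these ratios are not like for like with 1.74 or with each other. Without D. persimilis the obscura group is a single library, and the genes counted are those that set it apart.

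**Figure D2:**
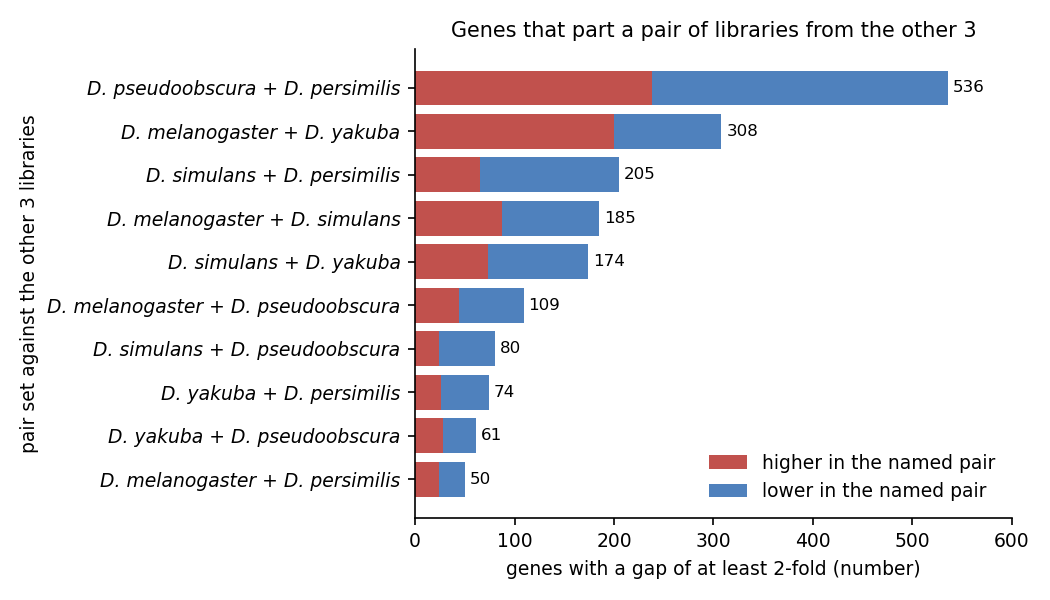
Number of genes (horizontal axis) with a gap of at least 2-fold between a pair of libraries and the other 3, for each of the 10 pairs (vertical axis), with genes higher in the pair in red and lower in the pair in blue and the total at the end of each bar. The pair D. pseudoobscura and D. persimilis has 536 genes, against 308 for D. melanogaster and D. yakuba.

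Single genes differed widely between the species groups. UQCR-14L (CG17856), a relative of a respiratory complex III subunit, had signals of 4508 and 6525 in D. pseudoobscura and D. persimilis, against 0.146, 0.442 and 0 in the others. Whether the same gene copy was matched in all species is not known, for this gene or for other members of gene families. The fatty acid desaturase Desat2, which acts in hydrocarbon pheromone synthesis, had 348 and 428, against at most 2.19. The odorant-binding proteins Obp49a (468 and 400 against at most 37.1) and Obp58c (206 and 176 against at most 7.20) and the odorant receptors Or88a (23.0 and 18.2 against at most 2.12) and Or74a (101 and 49.3, listed at 0 in the other 3) were also higher, while of 24 odorant-binding protein genes, a family counted after seeing the data, 4 were higher and 6 lower by the 2-fold gap. In the other direction, the odorant-binding protein Obp56e, at 149, 1478 and 515 in the melanogaster group, was listed at 0 in both obscura group libraries, and UGP, which makes UDP-glucose, was at 189, 530 and 432 against 1.46 and 3.13.

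In all, 238 genes were higher and 298 lower in the obscura group by the 2-fold gap. Under equal library totals the counts were 157 and 350, and under scaling by TMM and by median of ratios they were 263 and 278, and 277 and 266. Among genes with a mean of at least 20 they were 182 and 151. Leaving out 1 library gave 366 and 401 without D. melanogaster, 399 and 522 without D. simulans, 354 and 417 without D. yakuba, 486 and 739 without D. pseudoobscura, and 427 and 634 without D. persimilis. The counts without D. pseudoobscura and without D. persimilis rest on a single obscura group library. Further named genes with the largest gaps upward were the tetraspanin Tsp42Ed (3863 and 3988 against at most 540), the cytochrome P450 Cyp6a19 (171 and 304 against at most 7.66), the serpin Spn100A (25.1 and 86.3), CheB98a (132 and 17.1) and RpS28-like (74.6 and 45.2), the last 3 listed at 0 in the melanogaster group, and Gar1, a component of small nucleolar ribonucleoproteins (36.5 and 86.7 against at most 1.89). Downward, the peptidase relative Ance-4 (58.9, 60.9 and 176 against 0.513 and 0.119), the tetraspanin Tsp42Er (68.7, 62.3 and 27.0 against 0 and 0), the exosome subunit Rrp46 (16.2, 46.6 and 25.0 against 0 and 0), the deubiquitinase Josd (26.0, 35.6 and 21.9 against 0.348 and 0), the cathepsin CtsL2 (14.6, 61.1 and 13.6 against 0 and 0), the peroxisomal transporter Abcd3 (64.7, 55.1 and 22.4 against 0.434 and 1.15), the transporter MFS10 (23.8, 41.0 and 17.5 against 0.498 and 0), RN-tre (15.7, 26.2 and 26.9 against 0.663 and 0.433) and Yeti (628, 340 and 242 against 19.2 and 24.5) had the largest gaps. Rootletin, which builds the rootlets of chordotonal cilia, was at 15.3, 24.5 and 13.5 in the melanogaster group and at 0 and 0.0674 in the obscura group. A level of 0 in this table can be a missing match between annotations, since the widely expressed 14-3-3zeta was listed at 0 in D. simulans and SkpA and the general transcription factor Tbp at 0 in D. persimilis.

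Among genes above 0 in all 5 libraries, 182 were higher and 223 lower in the obscura group. Higher ones included the maltase Mal-B2 (1676 and 839 against at most 145), OS9 (11118 and 15684 against at most 1947), the calcium-binding protein Scp2 (1305 and 1099 against at most 195), Dtwd2 (29.9 and 41.1 against at most 4.52), THG (39.2 and 35.7 against at most 6.45), the aminopeptidase ApepP (48.4 and 47.7 against at most 7.76), the selenophosphate synthetase relative Sps1 (76.3 and 106 against at most 13.7), the cytochrome P450 Cyp6t3 (610 and 221 against at most 47.8), and the glutathione transferase GstD8 (176 and 1043 against at most 38.9). Lower ones included the aminotransferase Agxt (13.9 and 14.1 against at least 135), the Fos transcription factor kayak (kay; 3.53 and 4.37 against at least 37.7), the mitochondrial carrier Bmcp (0.476 and 4.21 against at least 35.4), the zinc finger factor wings down (wdn; 0.208 and 1.38 against at least 15.03), Svil (0.362 and 0.333 against at least 11.7), the kinase Aduk (0.828 and 0.0779 against at least 11.8) and c12.2 (0.776 and 0.808 against at least 11.5).

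By gene group, genes of the olfactory segment of the antenna were higher in the obscura group, with a median log2 difference of 0.93 over 19 members (percentile 99.5 among 10000 expression-matched random lists). Of these members 2 were higher by the gap rule, Or88a and Obp28a (25853 and 13511 against at most 5172), and 2 lower, Obp56d (706 and 618 against at least 1997) and Obp99a (0 and 6.90 against at least 60.7). Fat body and haemolymph genes were lower (median -0.98, percentile 0.18, 16 members), with the yolk proteins Yp1 (1744 and 1015 against at least 3807) and Yp2 (470 and 79.1 against at least 2664) and the mitochondrial trifunctional enzyme subunit Mtpalpha (37.2 and 26.2 against at least 111) lower by the gap rule. Antimicrobial and immune genes were lower (-1.12, percentile 0.14, 17 members; the serpin necrotic at 32.2 and 29.9 against at least 134, and pirk, at 0 and 0 against at least 2.92), as were haemocyte genes (-1.38, percentile 0.68, 8 members; CG5002 at 7.17 and 8.76 against at least 29.9) and heat shock and stress genes (-0.94, percentile 1.23, 12 members; the glutathione transferase GstD1 at 358 and 310 against at least 1244, and the co-chaperone starvin at 13.1 and 5.15 against at least 39.5). Phototransduction genes were lower still (-2.57, percentile 0, 17 members, with 7 lower and the carotenoid oxygenase ninaB higher), and their levels in D. simulans were part of that difference. Of these 17 genes 10 were listed at 0 in at least 1 library, and the median was -1.54 (percentile 0.755) over the 7 above 0 in all 5. The calls rested on single libraries in several lists. Without D. simulans the medians and percentiles were -1.32 and 3.75 for phototransduction, 0.66 and 94.3 for olfactory genes, -0.72 and 2.67 for immune genes, -1.06 and 3.04 for haemocytes and -0.58 and 8.78 for heat shock genes. Without D. pseudoobscura the olfactory list was at 0.81 (95.1), and without D. melanogaster the fat body list was at -0.55 (6.50). Heat shock genes were also inside the random range without D. yakuba (3.30), without D. persimilis (3.84), among genes with a mean of at least 20 (23.5) or above 0 in all libraries (5.27), against unmatched random lists (3.06) and with a trend on gene length removed (9.38).

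With all libraries and compared genes in, the other lists lay inside the range of the expression-matched random lists in this contrast. Glia (-0.83, percentile 5.35) and axonemal dynein genes (-1.08, percentile 3.69) reached percentiles of 0.42 and 1.51 without D. simulans, and the dynein list stood apart under equal totals (2.02) and against unmatched random lists (1.38). Ciliogenesis genes (0.28, percentile 90.8) reached 97.7 without D. yakuba, and the 7 with a mean of at least 20 had a median of 2.12 (percentile 99.96), but the median turned to -0.37 (52.8) without D. simulans and -0.10 (66.1) without D. pseudoobscura. Cytosolic ribosomal proteins (0.56, percentile 95.9, 47 members) reached 98.0 without D. simulans, 99.4 without D. persimilis, 97.7 with no expression filter and 99.8 against unmatched lists. The mitochondrial respiratory chain (0.25, or -0.02 under equal totals, percentile 46.0) moved to -0.58 and a percentile of 0.83 without D. persimilis. Chordotonal support genes (-0.15, percentile 44.4), transcription factors (-0.21, percentile 51.9), synaptic genes (0.17, or -0.09 under equal totals, percentile 70.7), muscle (0.28, percentile 65.1, 1 lower), detoxification enzymes (-0.05, or 0.07 under median-of-ratios scaling and 0.01 under TMM scaling, percentile 33.8, 2 lower) and clock genes (-0.50, percentile 14.9, 1 lower) did not stand apart with any 1 library left out. Their directions were not stable: medians turned to as much as 0.44 for chordotonal support, 0.13 for clock genes and -0.15 for muscle without D. persimilis, 0.45 for transcription factors and 0.11 for detoxification without D. melanogaster, and -0.50 for synaptic genes without D. simulans. Housekeeping references (-0.24, percentile 20.8, 11 members) stayed inside the random range in all 5 such runs.

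Phototransduction genes, which act in photoreceptors and of which several are also known from Johnston's organ, were far higher in the D. simulans library than in the D. melanogaster library. Among 17 phototransduction genes 12 were at least 4-fold higher in D. simulans and none was 4-fold lower, with a median log2 difference of 4.61 (percentile 100). The major rhodopsin gene ninaE was at 4604 in D. simulans against 56.3 in D. melanogaster, and its level in the other 3 libraries was 159, 13.5 and 26.5. The arrestins Arr2 (2172 against 38.4) and Arr1 (470 against 6.88), the rhodopsins Rh4 (367 against 6.30), Rh6 (93.5 against 1.38) and Rh5 (74.2 against 1.39) and the light-activated channel trp (87.4 against 2.62) followed it. Immune genes had a median of 1.45 (percentile 99.9), with 7 of 17 at least 4-fold higher, and did not stand apart among genes with a mean of at least 20 (0.28, percentile 54.7), above 0 in all libraries (percentile 95.99) or of middle exon length (89.5). The 7 included Defensin (Def; 319 against 2.46), AttD (119 against 5.11) and the Dso1 peptide gene (11442 against 1384).

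Axonemal dynein genes and antennal transcription factors were lower in D. simulans than in D. melanogaster. Axonemal dynein and dynein assembly genes had a median of -1.88 (percentile 0.36), with 6 of 13 at least 4-fold lower, among them Ccdc114 (0.104 against 17.5), Dnaaf3 (0.0915 against 15.1) and Dnai2 (11.7 against 78.6). Of 5 transcription factors of the antenna and chordotonal organs 4 were 4-fold lower, with a median of -3.68 (percentile 0.21): Distal-less (Dll; 0.603 against 22.4), spineless (ss; 0.966 against 26.5), prospero (pros; 0.159 against 13.8) and onecut (0 against 7.09). Chordotonal support genes had a median of -1.99 (percentile 0.20, 4 of 8 lower), with pio at 18.9 against 113 and beta-Spectrin at 11.6 against 60.5, but lay inside the random range with a smooth trend on gene length removed (-1.09, percentile 4.86). Synaptic genes had a median of -1.11 (percentile 1.57, 3 of 14 lower; the hyperpolarization-activated channel Ih at 6.02 against 51.9), which became -0.29 (percentile 36.5) with the length trend removed, and did not stand apart among genes with a mean of at least 20 (percentile 8.58) or above 0 in all libraries (7.78). Glial genes (-1.39, percentile 0.92, 4 of 12 lower and 1 higher; the transporter Mdr65 at 0.608 against 69.9, the astrocyte gene alrm at 26.7 against 1.54), circadian clock genes (-1.41, percentile 0.58, 4 of 11 lower; Clk at 0.148 against 10.99) and detoxification enzymes (-0.85, percentile 0.28, or 7.27 against unmatched lists, 4 of 12 lower; Ugt35A1 at 16.9 against 220) were also lower. Ciliogenesis genes had a median of -1.17 at a percentile of 5.03, or -1.12 at 2.36 with the length trend removed, with 6 of 20 lower and 2 higher, and BBS4, a subunit of the ciliary BBSome, was at 0.102 against 42.6.

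Muscle genes were higher in D. simulans (median 1.38, percentile 98.5, or 96.4 among genes with a mean of at least 20), with 6 of 14 at least 4-fold higher, such as myofilin (Mf; 15632 against 404), the myosin light chains Mlc1 (9593 against 921) and Mlc2 (8233 against 977) and flightin (fln; 2728 against 302). Haemocyte genes were higher as well (1.25, percentile 99.1), with 3 of 8 past 4-fold, PPO1 (508 against 57.4), PPO2 (576 against 123) and NimB3 (569 against 76.3). Fat body genes had a median of -0.11, or 0.26 under median-of-ratios scaling (percentile 16.5), and within this list fit (24996 against 1174) and Obp99b (7558 against 361) were 4-fold higher while the storage proteins Lsp2 (11.1 against 494) and Lsp1beta (0.459 against 26.3) were 4-fold lower. Heat shock genes lay at 0.89 (percentile 95.9, or 1.16 and 99.5 with the length trend removed), with 4 of 12 higher, including Hsp26 (1923 against 42.6). Hsp22, also among the 4, was listed at 0 in D. melanogaster, where 100% of its exonic bases are shared with another gene. Respiratory chain genes (1.49, percentile 89.6, 6 higher and 1 lower of 25), ribosomal proteins (1.44, percentile 95.2, 13 higher of 47) and housekeeping references (0.08, or -0.82 under equal totals, percentile 19.4) did not stand outside the matched random lists, nor did olfactory genes (-0.18, percentile 12.7, 2 higher and 1 lower of 19). Against unmatched lists the respiratory chain and the ribosomal proteins both reached percentile 100.

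Among single genes, the largest differences upward in D. simulans were for Prx5, a peroxiredoxin (3956), the small heat shock protein Hsp22 (3158), the serine proteases Jon25Bi (1625 against 0.680) and Jon25Bii (494), slowmo (slmo; 853 against 0.127), the mitochondrial import protein Tim10 (675), the phosphatase primo-1 (425), the enzyme Argl (413), the immune-induced peptide gene IM18 (362) and the signal peptidase subunit Spase12 (316), of which those with 1 value were listed at 0 in D. melanogaster. Of these, Prx5, Hsp22, slmo, Tim10, primo-1, IM18 and Spase12 were also at least 20 in the other 3 libraries and have most of their exonic bases shared with a neighbouring gene in the D. melanogaster annotation. Among genes above 0 in all libraries, Listericin, an antibacterial peptide gene (2486 against 21.9), Hsp67Bc (152 against 0.464), Hsp67Bb (53.0 against 0.186) and vnc (115.3 against 0.145) were among the highest. The D. melanogaster levels of Hsp67Bc, Hsp67Bb and vnc rested on 7, 6 and 3 reads. Of the exonic bases of vnc, 93.2% are shared with another gene, so reads may have been left out there as well. Downward, yellow-h (2.06 against 251), the omega-class glutathione transferase GstO2 (0.232 against 51.8), GlcAT-S (0.157 against 45.7), aspr (1.48 against 94.0), the receptor tyrosine kinase Tie (0.170 against 36.1), myoglianin (myo; 1.17 against 65.4) and the transcription factor cropped (crp; 0.235 against 33.8) had the largest differences, beside Lsp2, Mdr65 and BBS4. Listed at 0 in D. simulans were 14-3-3zeta (570 in D. melanogaster), Jon74E (121), the splicing factor SmF (91.0), Cyp9h1 (54.9), fuss (46.7) and obst-E (39.8).

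At the 4-fold rule, 467 genes were higher and 671 lower in D. simulans than in D. melanogaster, and 279 and 1298 under equal totals. The balance turned among genes with a mean of at least 20 (329 higher and 242 lower) and with a pseudocount of 5 (341 and 281). Long genes were lower and short genes higher in D. simulans, with a Spearman correlation of -0.325 between the difference and exon length across 5033 genes. With this trend removed phototransduction (5.02), axonemal dynein (-2.51), transcription factor (-2.93), glial (-1.08), muscle (1.95), haemocyte (2.02), immune (1.11), detoxification (-1.22) and clock genes (-1.18) stayed outside the random range.

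**Figure D3:**
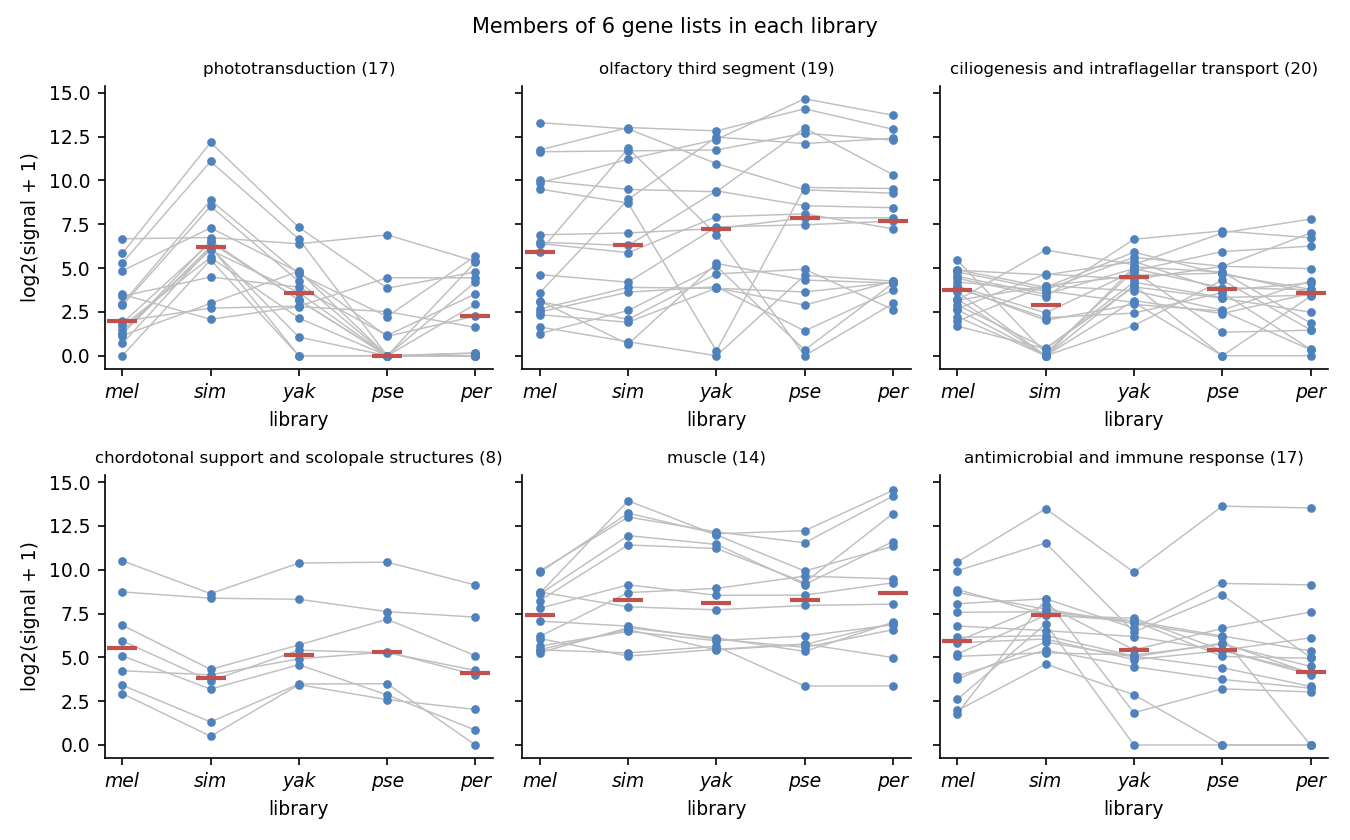
Level of each measured member of 6 gene lists (grey lines with blue points) in each of the 5 libraries (horizontal axis: D. melanogaster, D. simulans, D. yakuba, D. pseudoobscura, D. persimilis) as log2(signal + 1), with the median over members as a red bar and the number of members in brackets. Phototransduction genes are highest in D. simulans in 13 of 17 cases, and muscle genes are higher in D. simulans than in D. melanogaster by a median of 1.38.

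**Figure D4:**
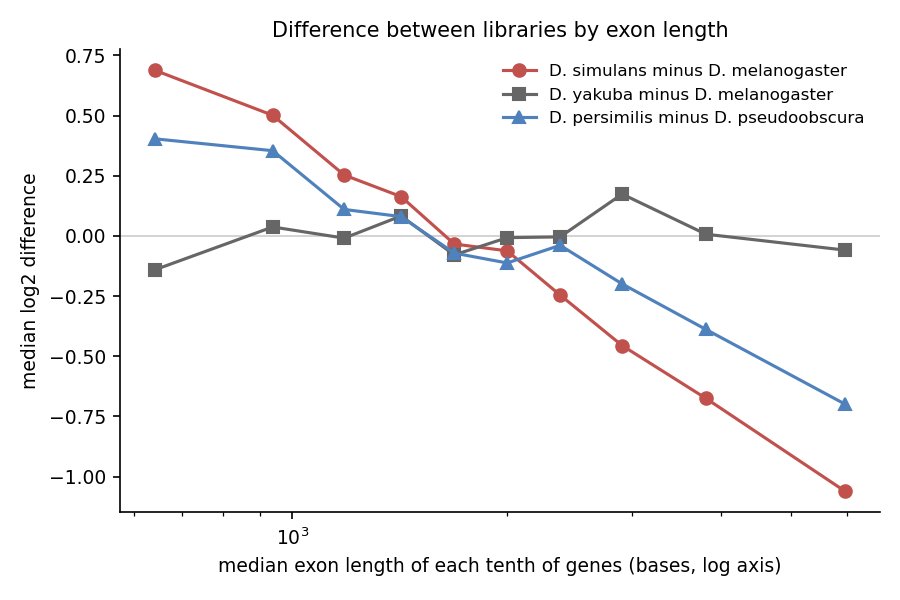
Median log2 difference between libraries (vertical axis) for genes sorted by D. melanogaster exon length into 10 bins, against the median exon length of the bin in bases (log axis), for D. simulans minus D. melanogaster (red), D. yakuba minus D. melanogaster (grey) and D. persimilis minus D. pseudoobscura (blue). The D. simulans difference runs from 0.69 to -1.06 and the D. persimilis difference from 0.40 to -0.70, while the D. yakuba difference has no such slope (correlation 0.0251).

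In the D. yakuba library, olfactory and ciliogenesis genes were higher than in the mean of D. melanogaster and D. simulans. The olfactory list covers another antennal segment than that of the organ, and whether such tissue was in a library was not tested. The olfactory list had a median log2 difference of 0.87 (percentile 99.985), with 6 of 19 members at least 4-fold higher and 2 lower. It was inside the random range among genes with a mean of at least 20. The odorant co-receptor Orco was at 678 against 88.0 in D. melanogaster and 77.3 in D. simulans, the odorant receptor Or42b at 162 against 23.8 and 17.3, the ionotropic co-receptor Ir25a at 37.5 against 7.72 and 0.585, and the odorant-binding protein Obp84a at 5696 against 11.1 and 483. Ciliogenesis genes had a median of 1.17 (percentile 99.9, 6 of 20 higher), among them IFT46 (32.5 against 5.22 and 0), the intraflagellar transport gene Oseg5 (17.4 against 2.22 and 0.319) and Chibby (Cby; 99.3 against 20.3 and 9.30). Against D. melanogaster alone, a comparison chosen after seeing the data, the olfactory list was at 1.43 (percentile 100) and the ciliogenesis list at 0.84 (99.9). Among genes of middle exon length the ciliogenesis list lay at 95.4 against the mean of both relatives. Axonemal dynein genes (1.01, percentile 98.5, 3 of 13 higher and Dnali1 lower at 1.13 against 26.8 and 19.5) and synaptic genes (1.01, percentile 99.7, none of 14 past 4-fold) stood above the mean of both relatives, which holds the low D. simulans values, and did not stand apart from D. melanogaster alone (-0.05, percentile 45.3, and 0.34, percentile 87.5). Against the mean of both, the dynein list was inside the random range among genes with a mean of at least 20. The synaptic list was inside it with the length trend removed (0.61, percentile 93.9).

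Fat body genes were lower in D. yakuba (median -1.52, percentile 0), with 6 of 16 at least 4-fold lower: Lsp2 (0.0888 against 494 and 11.1), Lsp1beta (0.0552 against 26.3 and 0.459), Fbp2 (0.170 against 13.2 and 3.85), the circadian feeding gene takeout (to; 483 against 3832 and 1340), Obp99b (88.1 against 361 and 7558) and fit (206 against 1174 and 24996). Immune genes were lower (-1.10, percentile 0.03, 4 of 17), including Metchnikowin (Mtk; 86.6 against 982 and 2949) and AttD (0 against 5.11 and 119). Against D. melanogaster alone these lists were at -1.17 (percentile 0.02) and -0.58 (1.84). Among genes of middle exon length the immune list lay at 22.5 against the mean of both relatives. Phototransduction genes were lower against the mean of both relatives (-1.26, percentile 0.01, 3 of 17 lower and laza higher), which includes the high D. simulans values, and higher than in D. melanogaster alone (0.86, percentile 99.3), with ninaE at 159 against 56.3 and 4604. Among genes above 0 in all libraries the list did not stand apart from the mean of both relatives. The chordotonal support list (0.70, percentile 92.3), transcription factors (0.93, percentile 88.1), glia (0.72, percentile 96.6, 4 of 12 higher), muscle (0.21, percentile 88.2), haemocytes (-0.03, or 0.16 under equal totals, percentile 43.8), heat shock (0.20, percentile 68.2), detoxification (-0.03, or 0.14 under equal totals, percentile 54.3), respiratory chain (-0.08, or 0.10 under equal totals, percentile 47.3), clock (-0.23, percentile 17.4), housekeeping (0.43, percentile 93.3) and ribosomal protein lists (0, percentile 73.9) did not stand apart from this mean, though muscle (0.79, percentile 98.8) and heat shock genes (0.80, percentile 98.5) stood above D. melanogaster alone.

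Of single genes, 73 were at least 4-fold higher in D. yakuba than in both relatives and 125 lower. The highest were Orcokinin, a neuropeptide gene (62.6 against 0.101 and 0), Obp56c (40.2 against 0 and 0), Kaz-m1 (208 against 10.6 and 1.89), wun2 (16.3 against 0.0998 and 0), the acyl-CoA binding protein Acbp5 (197 against 0.971 and 15.5), AANATL7 (11.1 against 0 and 0.181), the glycosyltransferase Pgant4 (32.2 against 2.26 and 0.0733), the fucosidase Fuca (81.2 against 4.96 and 8.05), the tyrosine kinase Btk (52.2 against 4.87 and 2.15), the midline glia gene wrapper (35.8 against 3.22 and 0.594) and Or43a (33.4 against 1.41 and 4.99). The lowest were Cyp6w1 (0.210 against 727 and 418), RpS27A (9.05 against 3103 and 5080), Cyp6d5 (1.42 against 503.6 and 132), tobi (0 against 45.2 and 52.5), tut (0 against 19.3 and 45.4), Hpd (9.92 against 196 and 211), the RNA polymerase subunit Polr2F (19.7 against 387 and 278), Rcd4 (1.08 against 23.6 and 89.1) and Edem1 (0.111 against 11.5 and 15.7). RpS27A, a ribosomal protein, was at 3648 in D. pseudoobscura and 4814 in D. persimilis. Among genes above 0 in all libraries the counts were 36 higher and 90 lower, and with a pseudocount of 5 they were 39 and 47. With the length trend removed synaptic genes were at a percentile of 93.9, among genes above 0 in all libraries phototransduction was at 20.2, and among genes with a mean of at least 20 olfactory genes were at 97.1 and axonemal dynein genes at 97.4.

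Between the obscura group species, muscle and respiratory chain genes were higher in D. persimilis than in D. pseudoobscura. The muscle list had a median log2 difference of 1.11 (percentile 99.99), and 4 of 14 members were at least 4-fold higher, flightin (9427 against 616), Mlc2 (18825 against 2974), TpnC4 (3122 against 568) and Mlc1 (23698 against 4789). The respiratory chain list had a median of 1.18 (percentile 99.98), and the 2 of 25 past 4-fold were ATPsynC (28813 against 4329) and the succinate dehydrogenase subunit SdhC (7398 against 1775). The 4 seminal fluid genes of the Acp53 cluster were highest in D. persimilis and at most 1.98 in the other libraries, with Acp53C14b at 501, Acp53C14a at 344, Acp53Ea at 193 and Acp53C14c, named after its values were seen, at 31.7, and all 4 were listed at 0 in D. pseudoobscura.

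Chordotonal support genes were lower in D. persimilis (median -1.31, percentile 0.52), though not outside the random range with a trend on gene length removed (-0.82, percentile 4.11), with 3 of 8 past 4-fold: the non-muscle myosin zipper (zip; 0.803 against 6.25), pio (33.1 against 143) and crumbs (crb; 0 against 10.3). Immune genes (-0.50, percentile 1.93, or 4.16 with a pseudocount of 5; Mtk at 30.9 against 375 and Diptericin B at 0 against 70.3) and fat body genes (-0.37, percentile 1.90, or -0.14 and 28.4 with the length trend removed and 30.7 with no filter; Yp2 at 79.1 against 470 and Fbp2 at 0 against 35.4 lower, CG14400 at 334 against 22.2 higher) were lower at the main setting, and neither stood apart against unmatched lists (6.88 and 13.5). Phototransduction genes had a median of 0.14 (percentile 81.5), with 5 of 17 at least 4-fold higher, led by Arr2 (40.1 against 0) and Arr1 (50.7 against 3.71). No difference outside the random range was seen for axonemal dynein (-0.13, percentile 44.8), ciliogenesis (-0.06, percentile 58.3), transcription factors (-1.07, percentile 9.27), synapse (-0.53, percentile 10.2), glia (-0.52, percentile 6.71), olfactory (-0.11, percentile 10.9), haemocyte (-0.66, percentile 7.49), heat shock (-0.05, or 0.02 under median-of-ratios scaling, percentile 36.3), detoxification (-0.17, percentile 12.6), clock (-0.16, percentile 38.1), housekeeping (-0.19, percentile 6.47) and ribosomal protein genes (0.32, or -0.11 under equal totals, percentile 20.5).

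Other genes far higher in D. persimilis were the testis-biased proteasome subunit relative Rpt6R (122 against 0), Cp15 (93.3 against 0), the maltases Mal-A1 (69.3 against 0) and Mal-A6 (97.2 against 4.26), the chromatin protein Bap111 (95.3 against 0.524), Gpxl (58.9 against 0), hng1 (46.8 against 0), SmydA-6 (50.2 against 0.0962), Peritrophin-15a (318 against 9.28), Kaz-m1 (250 against 7.53), MME1 (31.2 against 0.325), the copper transporter Ctr1B (24.6 against 0.273), easily shocked (eas; 23.1 against 0.287), rtet (18.7 against 0.0917) and the vesicular GABA transporter VGAT (18.6 against 0.0873). Far lower were SkpA, a ubiquitin ligase component (0 against 319), obst-E (0.481 against 80.8), the flap endonuclease Fen1 (0.0944 against 38.2), wat (0 against 29.2), casp (0.259 against 33.3), replication protein A (RPA1; 0 against 24.8), pen (0.0534 against 26.1), the kinase Cdk7 (0 against 22.7), MFS15 (0.0732 against 23.4), yata (0.292 against 27.5), Tango14 (2.30 against 62.8), the glial factor repo (0.885 against 33.2), Ets98B (0.0698 against 18.04), Dgp-1 (1.81 against 48.1), Sex lethal (Sxl; 0.676 against 26.1) and drop dead (drd; 1.47 against 35.8). In total 366 genes were at least 4-fold higher and 408 lower, 271 and 591 under equal totals, 158 and 129 among genes with a mean of at least 20, and 162 and 135 with a pseudocount of 5. The difference had a correlation of -0.260 with exon length.

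Of the pairs between more distant species, D. pseudoobscura had 484 genes at least 4-fold higher and 648 lower than D. melanogaster (371 and 933 under equal totals), and D. persimilis 610 and 787 (351 and 1460 under equal totals). D. yakuba had 307 higher and 285 lower than D. melanogaster (272 and 406 under equal totals) and 609 and 415 against D. simulans (995 and 232). Against D. simulans, D. pseudoobscura had 736 and 665 (983 and 505) and D. persimilis 650 and 681. Against D. yakuba, D. pseudoobscura had 466 and 616 and D. persimilis 549 and 735 (331 and 1128). Several of these balances turned in other settings. Among genes with a mean of at least 20, D. pseudoobscura had 328 higher and 277 lower than D. melanogaster, and D. persimilis 445 and 332. Against D. yakuba the same libraries had 285 and 270, and 379 and 300, and against D. simulans 351 and 356, and 338 and 340, while D. yakuba against D. simulans had 230 and 263. With a pseudocount of 5, D. persimilis had 454 and 392 against D. melanogaster and 381 and 352 against D. yakuba. D. persimilis also had more genes higher than lower against D. melanogaster under median-of-ratios scaling (715 and 653), and D. yakuba fewer among genes above 0 in all libraries (170 and 210).

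Over all 5 libraries, 4 lists varied more than their expression-matched random lists: phototransduction, with a median SD of 2.58 on the log2 scale (percentile 100), heat shock and stress (1.80, percentile 99.95), genes of the olfactory segment (1.48, percentile 99.8) and fat body (1.33, percentile 99.0). Transcription factors (1.57, percentile 62.1), ciliogenesis (1.49, percentile 94.8) and axonemal dynein genes (1.43, percentile 87.4) had median SDs as large as some of these, inside the range of their random lists. Hsp26 (42.6, 1923, 83.9, 26.8 and 73.6) was an example. The fat body list lay at 95.3 against unmatched lists. In restricted sets the percentile of phototransduction was 88.4 among genes above 0 in all libraries, and those of the olfactory and fat body lists were 84.2 and 95.5 among genes of middle exon length, a set chosen after seeing the data.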

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

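Of the tests below, the share of phototransduction genes highest in D. simulans was chosen only after its result was seen.

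A large part of the D. melanogaster reads lay on genes that could not be matched to the cross-species table. Of 22391819 reads, 9202988 were counted on such genes, 41.1% (Wilson 95% interval 41.08 to 41.12, for counting error only). This share is an upper limit for genes outside the table, because 343 of the 8180 table genes, Cyt-c-p among them, had no matched count under the later annotation. From their signals, 250 of these with a known exon length would hold about 825349 reads, and the other 93, taken at the median exon length of 1866 bases, about 439300, which would leave 35.5% outside. The unmatched genes included 4184 with more than 3 reads, and CG8369, Argk1, iav, btv and tilB were among them.

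Photoreceptor transcripts were higher in the D. simulans library, with a median log2 difference from D. melanogaster of 4.61 over 17 genes. The tables argue against library scaling as the whole cause, since the smallest median over the 3 other scalings was 3.85, and against gene length, since the median was 5.02 with the length trend removed. Eye tissue in this library may be a source, but the share of genes highest in D. simulans (13 of 17, 76.5%, against 23.3% of all compared genes) restates the pattern and does not decide it. No compared gene of this list is in another list, the D. melanogaster library itself held 1375 ninaE reads, and of the other eye and pigment genes v was highest in D. simulans (124) while Pu (10.3) and boss (7.72) were lowest there. Lists of other tissues also differed between these 2 libraries. Muscle (1.38) and haemocyte genes (1.25) were higher in D. simulans, and glial genes (-1.39) and antennal transcription factors (-3.68) lower. Eye tissue and a species difference in the organ's own expression of the phototransduction genes cannot be told apart, because there is 1 library of the species.

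A set of 55 genes was at or below 1 in D. melanogaster and at least 20 in each other library, against 10 such genes for D. simulans, 2 for D. yakuba, 8 for D. pseudoobscura and 5 for D. persimilis. Too few reads cannot account for it, since the D. melanogaster library would have held a median of 1150 reads on these genes at the lowest level of the other libraries. Of 54 with an annotation, 79.6% share most of their exonic bases with another gene on either strand, against 1.80% of 1718 other genes of at least 20 in the other 4 libraries. This is consistent with reads being left out where D. melanogaster gene models overlap. Prx5, Hsp22, slmo, Tim10, primo-1, IM18, Spase12 and vnc belong to the overlapping genes, and Argl, with 9.08% of its bases shared, does not.

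Genes with long transcripts were lower in D. simulans than in D. melanogaster (correlation of the difference with exon length -0.325), in D. persimilis than in D. pseudoobscura (-0.260) and in D. pseudoobscura than in D. melanogaster (-0.213), so that the trend also enters the contrast of species groups. Lower depth did not produce the D. simulans trend, since D. melanogaster counts thinned to the D. simulans total gave a correlation of 0.0107 over 4866 genes. Short genes being the highly expressed ones can account for at most a part of the trends. The correlations for D. simulans and D. persimilis were -0.247 and -0.233 at equal mean expression over 5033 genes, against -0.325 and -0.260 without it. Exon lengths were those of D. melanogaster, while each library was counted on the annotation of its own species. The gene models of these annotations, RNA quality, library preparation and species differences stay open and were not tested.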

How the results depend on the processing

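The alternatives that depend on exon length, D. yakuba against D. melanogaster alone, and the lists with single libraries left out, were chosen after seeing the data. No paired analysis was possible because each species has 1 library. Counts of each library's own annotation were not run as an alternative, since their identifiers are not tied between species here. TMM, median-of-ratios scaling, a pseudocount of 0.5, Pearson correlation and unmatched random lists moved none of the counts and correlations by which libraries were compared past the limits set (1.5 times, or 0.1 for a correlation). Where genes or libraries are fewer, or a threshold differs, the count differs by construction; for other changes the cause was not tested. Pairs are in the order D. melanogaster with D. simulans, D. yakuba, D. pseudoobscura and D. persimilis, D. simulans with D. yakuba, D. pseudoobscura and D. persimilis, D. yakuba with D. pseudoobscura and D. persimilis, and the obscura pair.

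With a pseudocount of 5 the genes at least 4-fold apart numbered 622, 343, 686, 846, 516, 847, 779, 607, 733 and 297. With a mean of at least 20 they numbered 571, 333, 605, 777, 493, 707, 678, 555, 679 and 287, and 151 genes were lower in the obscura group. Among genes of middle exon length they numbered 525, 289, 538, 631, 468, 695, 672, 504, 539 and 391, with 105 genes higher and 130 lower in the obscura group and 14 combinations of list and contrast standing apart. At a 2-fold threshold they numbered 2544, 1757, 2487, 2848, 2442, 2790, 2741, 2479, 2671 and 2021. With no filter the obscura pair had 1180, and the first 9 correlations were 0.813, 0.859, 0.796, 0.777, 0.847, 0.791, 0.799, 0.827 and 0.817. Among genes above 0 in all libraries D. melanogaster and D. yakuba had 380. A 4-fold gap left 73 genes higher and 104 lower in the obscura group. Equal totals gave 157 higher genes and turned the ratio of the species-group split to the next from 1.74 to 0.988. The 73 genes higher and 125 lower in D. yakuba became 39 and 47 with a pseudocount of 5, 153 and 148 with no filter, 30 and 74 with a mean of at least 20, 36 and 90 among genes above 0 in all libraries, and 37 and 54 among genes of middle exon length. Leaving out each library gave 354 to 486 higher genes, 401 to 739 lower genes and ratios of 1.01 to 4.61, from splits of unlike size.

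Among the list medians and named genes, 0 of 229 moved under TMM and median-of-ratios scaling, 3 under equal totals, 1 with a pseudocount of 0.5, 11 with a pseudocount of 5, 7 with no filter, 10 of 177 with a mean of at least 20, 7 of 169 among genes above 0 in all libraries, and 9 of 128 among genes of middle exon length. None of these that had been called turned its direction. Unmatched random lists left 34 combinations of list and contrast standing apart against 33, but 11 calls differed. Lost were detoxification (7.27) in D. simulans, fat body (13.5) and immune genes (6.88) in D. persimilis, heat shock (3.06) in the obscura group and fat body (95.3) in the SD. Gained were axonemal dynein (1.38) and ribosomal proteins (99.8) in the obscura group, ciliogenesis (0.48), respiratory chain (100) and ribosomal proteins (100) in D. simulans, and ciliogenesis (99.5) in the SD. Against D. melanogaster alone 4 of 18 list calls for D. yakuba moved, and phototransduction turned from low to high (99.3). Removing the length trend moved 9 of 72 list calls, and leaving out a library moved 8 of 18 without D. simulans, 3 without D. persimilis, 2 without D. yakuba, and 1 each without D. melanogaster and D. pseudoobscura. Depth limits low genes most in D. simulans, the library with the fewest reads.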

Other observations

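The families below were chosen after their values were seen, so their medians and counts describe these libraries and test nothing.

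The 15 odorant receptors past the expression filter were higher in the obscura group, with a median log2 difference of 2.05 (1.85 over 14 genes under equal totals). By the gap rule 4 were higher (Or43b, Or74a, Or88a and Or10a) and 0 lower. The filter has a part in this median and in these calls, of which only Or43b did not need its obscura group levels to pass. Or74a (0, 0, 0, 101 and 49.3), Or88a, Or45b, Or10a (1.93, 0, 0.483, 14.1 and 10.6) and Or82a (0, 7.58, 6.24, 16.2 and 24.8) passed it through their obscura group levels. Or65a (1.93, 20.8, 0.157, 0 and 3.82) passed it through D. simulans. The co-receptor Orco was highest in D. yakuba (678, against 376 in D. pseudoobscura and 348 in D. persimilis). Or43b, an odorant receptor of the antenna, was at 172 in D. pseudoobscura and 368 in D. persimilis against 10.5, 5.63 and 48.0 in D. melanogaster, D. simulans and D. yakuba. The 15 receptors were also higher in D. yakuba than in the mean of D. melanogaster and D. simulans (1.31, 6 higher and 1 lower). Odorant-binding proteins differed between the species groups by a median of 0.81 (24 genes, 4 higher and 6 lower in the obscura group by the gap rule), or 0.54 under equal totals and 0.28 with the length trend removed. Their median SD over the 5 libraries was 1.88, against 1.52 for 30 cytochrome P450 genes and 0.58 for 23 proteasome subunits.

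Cuticular proteins of the Cpr family were lower in D. simulans than in D. melanogaster (median -2.04, 7 of 11 lower and 1 higher), for example Cpr51A (11.9 against 153) and Cpr47Ee (15.2 against 141), and lower in D. yakuba than in their mean (-1.38, 4 lower and 2 higher). Cpr57A (21.7 against 0) was the 1 higher in D. simulans and was among the 2 higher in D. yakuba. In the D. melanogaster annotation 100% of its exonic bases are shared with another gene, so its 0 may be reads left out. Jonah proteases, digestive serine proteases, were higher in D. simulans than in D. melanogaster (2.56, 3 of 5 higher and 1 lower) and in D. persimilis than in D. pseudoobscura (3.001, 3 higher), with Jon25Bii at 494 against 0 and 350.1 against 42.9. Mitochondrial ribosomal proteins (52 genes) had medians of 0.71 for D. simulans minus D. melanogaster, 0.36 for D. persimilis minus D. pseudoobscura and -0.54 for D. yakuba minus the mean of its relatives. With the length trend removed these were -0.07, -0.06 and -0.06, and under equal totals -0.18, -0.06 and -0.36.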
